A study of Mus musculus with 16 samples.

How the data were processed

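RNA of 16 mouse liver samples was measured on Affymetrix GeneChip arrays, 1 array per sample: 7 Ctnnb1-mutated tumours and 3 control livers under phenobarbital, and 3 Ha-ras-mutated tumours and 3 control livers without it. The deposited values are log2 expression per probe set after RMA (background correction, quantile normalization between arrays and summary of probes into probe sets), made by the authors in R 2.14.1. All 45101 deposited probe sets were read without further scaling. The array files before RMA were not reprocessed, and no detection calls were used, so that low values may be background. The precision is set by the number of arrays, and the standard error of each fold change is given beside it. Samples were grouped by mutation and treatment as the labels give them. The labels write Ctnn1b for Ctnnb1 in 1 place, and their texts differ on the length and route of the phenobarbital course.

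Probe sets were named from the annotation of the platform, and names were checked against the Entrez identifiers of the RefSeq annotation of GRCm38.p6, which was used for names alone. Of the probe sets, 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 34741 of those with 1 symbol were matched by identifier, with 0 renamed. Per gene the probe set with the highest mean over all arrays was kept, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets of the Mup, Cyp2 and Gst families share sequence between members, so that the member measured is uncertain. Probe sets without a single gene name were left out of the gene tables and tested apart.

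Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group over all 16 arrays, then eBayes), with statmod 1.5 and data.table (version 1.17.8). There were 5 comparisons: Ctnnb1 tumours against phenobarbital controls, Ha-ras tumours against untreated controls, the difference between these changes as an interaction, phenobarbital against untreated controls, and Ctnnb1 against Ha-ras tumours. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. "Rose" and "fell" are used for genes that passed, and counts adjusted over a list alone use the members of that list. Calls shared by both tumour types were compared with the number expected from independent lists and tested with Fisher's exact test. The principal components were taken over all genes.

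Gene lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 38 lists of a comparison, and beside it with camera and an estimated correlation and with fry. There were 28 pathway and 10 cell type lists, written before the data were examined, and some share members. Named genes followed a rule also written before: per comparison the 7 largest rises and the 7 largest falls among genes that passed and whose arrays did not overlap between groups (for the interaction, those that passed), leaving out unnamed gene models. Ctnnb1, Hras, Glul, Axin2, Lgr5, Cyp2b10, Afp, Dusp6 and Mki67 were always named. Per list up to 4 passing members with the largest change, and up to 2 that went against the list, could be named. Which of the genes allowed by this rule are described was chosen after their values were seen, with preference for calls that held without any single array. Hras is not analysed here.

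The fit was tested on simulated data made from the spread of these arrays, with 200 changed genes per comparison. A further short list of genes was raised by a smaller step, and its members were not counted among the unchanged genes. The simulated noise was normal and independent between genes, no array stood apart, and fewer genes changed than passed in the tumour comparisons. Its rates may therefore not carry over to these data. At a log2 change of 1 it recovered 86 of 100 in the Ctnnb1 comparison, 87 in the Ha-ras comparison, 52 in the interaction, 72 between controls and 85 between tumours. At a change of 2 it recovered 96, 98, 94, 96 and 98. Unchanged genes made up 6.73%, 5.03%, 3.87%, 4.42% and 4.02% of the calls.

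Alternatives written before the data were examined were: only the arrays of the groups compared, the replicate number as a fixed or random block, dim genes left out, the mean of all probe sets, the probe set with the highest variance or every probe set, quantile normalization and median centring, eBayes with trend and robust, array weights, a 2-fold minimum, a threshold of 0.01 for shared calls, other list tests, each other probe set of a named gene, and each array left out in turn. Where this leaves few arrays in a group, the spread is pooled over all 4 groups. After the data were seen, 3 alternatives were added: phenobarbital control 6 and Ctnnb1 tumours 6 and 7 left out together, the gap between the 3′ and 5′ control probe sets of Gapdh as a covariate, and the arrays of each fixed block fitted without the block. Splits of the arrays into groups of the same sizes were counted, 100 at most, drawn with a fixed seed where there were more. Single arrays far from the others in the group of 7 were sought with Dixon's ratio (critical value 0.568). Counts of genes whose groups do not overlap are set against the share that chance gives.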

Results

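RNA from 16 pieces of mouse liver was read on Affymetrix GeneChip expression arrays, 1 array per sample. All came from male C3H/HeJ mice that, per the series design, were given the liver carcinogen diethylnitrosamine and then kept with or without phenobarbital, a barbiturate that activates the nuclear receptor CAR and promotes liver tumours. The arrays fall into 4 groups. There were 7 tumours with a mutation in Ctnnb1, the gene of beta-catenin, and 3 pieces of non-tumour liver labelled as their controls, all under phenobarbital. There were 3 tumours with a mutation in Ha-ras, the gene of a small GTPase that drives the ERK kinase cascade, and 3 pieces of non-tumour liver labelled as their controls, all without phenobarbital. The sample labels give 0.05% phenobarbital in drinking water for 27 weeks, while other label texts describe a different course. The title of the series names the metabolic programs of the activated Ha-ras and beta-catenin proteins as the subject. Mutation and phenobarbital therefore go together, and only tumour and control of 1 treatment differ in tissue alone. The values are log2 RMA intensities, so the number of arrays limits the precision, and the low end of the scale includes background. The array medians lay between 5.03 and 5.10. The transcript of Hras itself is not analysed here, and the level of Ctnnb1 mRNA does not show whether the gene is mutated. The labels do not state whether samples came from separate animals, so the tests measure the spread between samples. Per group, a mean is followed by its SD, and a log2 fold change by its standard error from the fit.

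The first 2 components of expression over all genes held 29.7% and 27.0% of the variance, and the Ha-ras tumours lay apart from the other 13 arrays on the second (−59.2 to −43.7, the others −10.3 or higher). On the first, the Ctnnb1 tumours lay between −43.6 and −21.8 and all other arrays between 13.0 and 35.7. Phenobarbital control 6 stood apart from controls 4 and 5. The gap between the 3′ and 5′ control probe sets of Gapdh, which widens when RNA is degraded, was 2.70 (log2) in that array and between −0.15 and 0.32 in the other 15. Its correlation with controls 4 and 5 was 0.978 and 0.979 across genes, against 0.993 between those 2.

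**Figure D1:**
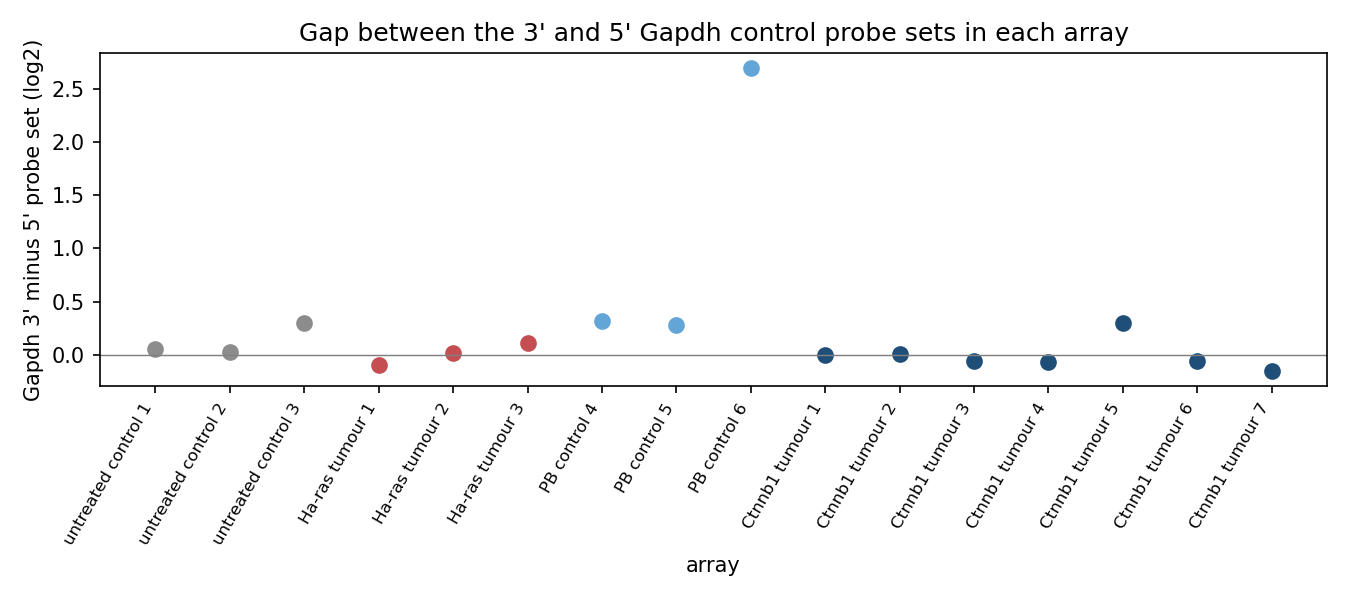
Difference between the 3′ and 5′ control probe sets of Gapdh (y axis, log2) in each of the 16 arrays (x axis), coloured by group; each point is 1 array. Phenobarbital (PB) control 6 stood at 2.70, and the other 15 arrays lay between −0.15 and 0.32.

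Ctnnb1 tumours were first compared with non-tumour liver under the same treatment (n = 7 and n = 3). Genes of hepatocytes near the portal vein were lower in the tumours: 14 of the 16 measured members of the periportal list fell and none rose (15 fell when adjusted over the list alone), with a median log2 fold change of −2.63 and an adjusted p of 0.124 with an estimated correlation. Etnppl, a phospholyase of phosphoethanolamine, fell from 12.40 ± 0.25 to 7.17 ± 0.91, a log2 fold change of −5.23 ± 0.61. Hal, the histidine ammonia-lyase, fell from 11.36 ± 0.30 to 7.01 ± 0.93, and Cyp2f2, a cytochrome P450, fell by 4.19 ± 0.83 on the log2 scale. On the same list Cps1, the carbamoyl phosphate synthetase, fell by 2.17 ± 0.37 and Arg1, the arginase of hepatocytes, fell by 2.95 ± 0.68. Afp, the fetal serum protein, rose from 7.64 ± 1.93 to 11.96 ± 0.75, a 20.1-fold difference, and Gpc3, a cell surface proteoglycan of liver tumours, rose 16.7-fold. The Afp difference was 41.5-fold without phenobarbital control 6 and 11.2-fold without phenobarbital control 4.

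Of 13 measured Wnt target genes 7 rose and none fell (10 rose when adjusted over the list alone), with a median of 1.17 (adjusted p = 0.246 with an estimated correlation). Lgr5, a receptor for R-spondin, rose by 2.57 ± 0.58 and Myc, the transcription factor, by 1.64 ± 0.35. Axin2, the feedback inhibitor of Wnt signalling, was higher by 1.27 ± 0.38 (adjusted p = 0.0423). Of 16 pericentral hepatocyte genes, those expressed around the central vein, 6 rose and none fell (10 rose when adjusted over the list alone), with a median of 0.90 (adjusted p = 0.246 with an estimated correlation). Lect2, a secreted protein, rose by 1.59 ± 0.25 and Gulo, the last enzyme of vitamin C synthesis, by 1.45 ± 0.22. Glul, the glutamine synthetase of pericentral cells, was at 13.60 ± 0.69 in tumours and 12.51 ± 1.19 in controls (adjusted p = 0.126), while its other probe set rose (2.34, adjusted p = 0.0406). Ctnnb1 tumour 6 lay below the other 6 tumours in both groups of genes: its mean over the Wnt list was 6.56 against at least 7.62, and over the pericentral list 11.39 against 12.33 to 12.79. Without that tumour the Glul difference was 1.34 (adjusted p = 0.0261), and without phenobarbital control 4 it was 0.43. The other probe sets of Axin2 (0.15) and Lgr5 (0.19) did not pass. The Axin2 call was lost without any 1 of the other 9 arrays (adjusted p between 0.0530 and 0.123), and that of Lgr5 without phenobarbital control 4 (adjusted p = 0.0561).

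Enzymes of amino acid breakdown were also lower, with 15 of 25 members fallen and none risen (17 fallen when adjusted over the list alone) and a median of −0.94 (adjusted p = 0.246 with an estimated correlation). Gldc, of the glycine cleavage system, fell by 3.53 ± 0.53 and Amdhd1, which acts after Hal in histidine breakdown, fell by 2.90 ± 0.37. Of 10 genes of gluconeogenesis and glucose export 7 fell and none rose, also when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation), among them Pck1, the cytosolic phosphoenolpyruvate carboxykinase (−3.02 ± 0.56), and Fbp1, the fructose bisphosphatase (−1.26 ± 0.21). In the urea cycle list 6 of 11 members fell and 1 rose, Glud1, the glutamate dehydrogenase, by 0.73 ± 0.19, a call lost without phenobarbital control 6 (0.33, adjusted p = 0.0772). The list as a whole did not pass (adjusted p = 0.0931). Of 13 male-biased liver genes 5 fell (6 when adjusted over the list alone), with a median of −1.03 (adjusted p = 0.339 with an estimated correlation). Susd4, a membrane protein, fell by 2.32 ± 0.27 and Cyp2u1, a P450, fell by 1.28 ± 0.24.

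Cell cycle genes were higher: 17 of 26 rose and none fell (21 rose when adjusted over the list alone), with a median of 1.15 (adjusted p = 0.246 with an estimated correlation). Nusap1, a protein of the mitotic spindle, rose by 2.46 ± 0.41, Ccnb2, a mitotic cyclin, by 2.27 ± 0.44 and Ube2c, of the ubiquitin system of mitosis, by 1.95 ± 0.39. Mki67, the proliferation marker, was at 7.67 ± 0.42 in tumours and 6.17 ± 0.88 in controls (adjusted p = 0.0366), a call lost without Ctnnb1 tumours 1, 2, 4 or 6 or without phenobarbital controls 4 or 5 (adjusted p up to 0.134). Of 12 NRF2 target genes 5 rose and none fell (7 when adjusted over the list alone; adjusted p = 0.246 with an estimated correlation), with Srxn1, the sulfiredoxin, up by 2.11 ± 0.45 and Gclm, of glutathione synthesis, by 0.82 ± 0.15. The mean of that list was highest in Ctnnb1 tumour 7, at 10.71 against 8.87 to 10.02 in the other 6. Of 15 fetal liver and tumour markers 5 rose, among them Afp, Gpc3 and Ly6d (3.40 ± 0.51), and 1 fell, Dlk1, a fetal liver protein (−0.43 ± 0.13), both counts unchanged when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). The Dlk1 call was lost in 8 of the 10 runs that left out 1 array, all but those without Ctnnb1 tumour 7 or phenobarbital control 5 (adjusted p up to 0.226).

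Of 20 phenobarbital (CAR) targets, 5 were higher in the tumours than in their controls and none fell (7 when adjusted over the list alone), with a median of 0.13 (adjusted p = 0.339 with an estimated correlation). Abcc4, an export pump, rose by 2.78 ± 0.61 and Gstm2, a glutathione transferase, by 1.79 ± 0.25, while Cyp2b10, the P450 used as the marker of CAR activity, was at 12.82 ± 0.31 in tumours and 12.62 ± 0.18 in controls (adjusted p = 0.814). The shift of this list was lost without Ctnnb1 tumour 2 (adjusted p = 0.0595), phenobarbital control 4 (adjusted p = 0.150) or dim genes, those below the median level (adjusted p = 0.0916). Of 18 cholesterol synthesis genes 2 rose (6 when adjusted over the list alone), with a median of 0.62 (adjusted p = 0.530 with an estimated correlation). The genes were Nsdhl (1.33 ± 0.37), whose call was lost without phenobarbital control 6 (0.79, adjusted p = 0.197), and Lss (0.97 ± 0.27), lost without Ctnnb1 tumour 1 or any 1 of the phenobarbital controls (adjusted p up to 0.124).

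Among markers of other cell types, 7 of 14 stellate cell and fibroblast genes fell and none rose, also when adjusted over the list alone (adjusted p = 0.281 with an estimated correlation). Lrat, the retinol acyltransferase of stellate cells, fell by 2.13 ± 0.31 and Dcn, the matrix proteoglycan decorin, fell by 2.04 ± 0.37. Of 13 endothelial markers 3 fell (6 when adjusted over the list alone), with a median of −0.74 (adjusted p = 0.436 with an estimated correlation), and of 6 cholangiocyte markers 1 fell (4 when adjusted over the list alone; adjusted p = 0.281 with an estimated correlation). The cholangiocyte shift was lost without Ctnnb1 tumours 3, 5 or 6 or phenobarbital controls 4 or 6 (adjusted p between 0.0519 and 0.150), and without that control and Ctnnb1 tumours 6 and 7 together (0.0888). Of 14 macrophage markers 2 fell, Clec4f, a Kupffer cell lectin (−1.95 ± 0.49), and Folr2, a folate receptor (−1.42 ± 0.28). The Clec4f call was lost without phenobarbital control 4 (−1.69, adjusted p = 0.0734), and the list did not pass (adjusted p = 0.101).

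Of 18193 genes, 2192 passed in this comparison, 1105 higher and 1087 lower in the tumours, 596 of them at least 2-fold. In 12.6% of all genes the tumours and the controls did not overlap, against 1.67% by chance. The largest rises among genes whose groups did not overlap, after Afp and Gpc3, were in Gipc2 (3.67), Aplnr, the apelin receptor (3.60), Calml4 (3.52), Arg2, the mitochondrial arginase (3.43), and Ly6d. The largest falls, after Etnppl, Hal and Cyp2f2, were in Olfm3 (−4.04), Aqp4, a water channel (−3.76), Aspg, an asparaginase (−3.73), and Rdh16f2, a retinol dehydrogenase (−3.72). Without phenobarbital control 4 the rises of Gipc2, Calml4 and Ly6d were 2.97, 2.88 and 2.77, and without control 6 Calml4 and Ly6d rose by 4.13 and 4.09. The level of Ctnnb1 was 12.42 ± 0.11 in tumours and 12.38 ± 0.13 in controls (adjusted p = 0.848). Its other probe sets were higher in the tumours by 1.14 and 0.61 without passing (adjusted p = 0.0861 and 0.101). By camera 14 of 38 lists shifted, 0 of them with an estimated correlation, and fry called 15. Without phenobarbital control 6 the count of genes was 1337, with the Gapdh gap as a covariate 836, and without that control and Ctnnb1 tumours 6 and 7 together 1383, of which 1073 were among the 2192. The covariate ended the calls of Lgr5 (adjusted p = 0.0548), Axin2 (0.0943), Myc (0.114), Gclm (0.0523), Srxn1 (0.0782), Clec4f (0.0621), Dlk1 (0.0947), Glud1 (0.445), Lss (0.264) and Nsdhl (0.474). The joint omission ended those of Myc (0.0982), Glud1 (0.137), Lss (0.115) and Nsdhl (0.203), while Glul passed (1.87, adjusted p = 0.00477). The mean of all probe sets ended those of Axin2 (0.0542) and Dlk1 (0.103). The covariate and the joint omission were chosen after seeing the data. Only phenobarbital control 6 had a wide gap, so the covariate comes close to leaving out that array. For Axin2 the change was 1.56 with the covariate and 1.49 without that control. The covariate is thus not a separate correction for RNA quality.

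Ha-ras tumours were compared with non-tumour liver without phenobarbital (n = 3 and n = 3). Fetal liver and tumour markers were higher: 10 of 15 rose and none fell (12 when adjusted over the list alone), with a median of 4.17. Akr1c18, a hydroxysteroid dehydrogenase, rose from 7.49 ± 0.42 to 12.54 ± 0.23, a 33.0-fold difference, and Spink1, a trypsin inhibitor, from 6.12 ± 0.63 to 11.10 ± 0.19. Bex1 rose by 5.23 ± 1.01, Tspan8, a tetraspanin, by 5.03 ± 0.74 and Afp by 4.17 ± 0.70. This shift held with an estimated correlation (adjusted p = 0.00584).

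Of 18 ERK feedback and target genes 11 rose and none fell (12 when adjusted over the list alone), with a median of 1.21 (adjusted p = 0.0559 with an estimated correlation). Dusp6, the phosphatase that inactivates ERK, rose by 2.57 ± 0.32 to 11.57 ± 0.31, and Spry2, an inhibitor of the pathway, rose by 2.45 ± 0.27. Of 12 immediate early genes 7 rose and none fell (8 when adjusted over the list alone; adjusted p = 0.0559 with an estimated correlation), with the transcription factors Egr1 up by 3.88 ± 0.26 and Fos by 2.38 ± 0.21. Of 26 cell cycle genes 13 rose (17 when adjusted over the list alone, where 1 fell), with a median of 0.93 (adjusted p = 0.294 with an estimated correlation), among them Ccnb2 by 2.58 ± 0.52 and Ccna2, the cyclin of DNA replication, by 1.98 ± 0.45. Mki67 rose by 2.06 ± 0.52, a call lost without untreated control 2 (adjusted p = 0.0626) or Ha-ras tumour 2 (adjusted p = 0.0702).

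Pericentral genes were lower in these tumours: 10 of 16 fell and none rose (13 when adjusted over the list alone), with a median of −1.95 (adjusted p = 0.0949 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 11.32 ± 1.23 to 8.19 ± 0.78, Slco1b2, a hepatic uptake carrier, fell by 3.03 ± 0.28 and Cyp1a2, a P450, fell by 2.62 ± 0.39. Glul was at 11.11 ± 0.57 in tumours and 12.45 ± 0.17 in controls (adjusted p = 0.110). Of 13 bile acid genes, some of them also on the pericentral list, 10 fell and none rose (10 fell and 1 rose when adjusted over the list alone; adjusted p = 0.0559 with an estimated correlation), among them Cyp8b1, a sterol hydroxylase (−3.57 ± 0.42). Of 13 male-biased genes 11 fell, also when adjusted over the list alone, with a median of −2.68 (adjusted p = 0.0631 with an estimated correlation), such as Cyp4a12a, a fatty acid hydroxylase (−3.80 ± 0.39). Of 10 female-biased genes 4 rose (5 when adjusted over the list alone, where 1 fell; adjusted p = 0.294 with an estimated correlation), such as Cyp17a1, of steroid synthesis, by 2.73 ± 0.43. The female-biased shift was lost without untreated control 2 (adjusted p = 0.0555) or dim genes (0.0804).

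In lipid metabolism 8 of 18 cholesterol synthesis genes rose and none fell (15 when adjusted over the list alone), with a median of 1.12 (adjusted p = 0.284 with an estimated correlation). Lss, the lanosterol synthase, rose by 2.36 ± 0.32 and Sqle, the squalene epoxidase, by 2.17 ± 0.38. Of 21 genes of fatty acid and triglyceride synthesis 7 rose (8 when adjusted over the list alone, where 1 fell; adjusted p = 0.457 with an estimated correlation), such as Pnpla3, a lipase of lipid droplets, by 2.28 ± 0.30, and that shift was lost without untreated control 3 (adjusted p = 0.200) or dim genes (0.0879). Of 25 amino acid breakdown genes 10 fell and none rose (12 when adjusted over the list alone; adjusted p = 0.294 with an estimated correlation), such as Prodh, the proline dehydrogenase (−3.57 ± 0.54), and Hpd, of tyrosine breakdown (−1.86 ± 0.33). Of 20 CAR targets 6 fell and 2 rose (7 and 3 when adjusted over the list alone; adjusted p = 0.294 with an estimated correlation), with Cyp2c50 lower (−2.99 ± 0.24) and Cyp2b9 higher (3.69 ± 0.76), both of them P450 genes. The CAR shift was lost without Ha-ras tumour 2 (adjusted p = 0.0625). Of 14 macrophage markers 5 fell, also when adjusted over the list alone (adjusted p = 0.457 with an estimated correlation), among them Clec4f (−2.46 ± 0.58), while the mean of that list in the Ha-ras tumours was 6.83, 7.04 and 8.80. Of 14 stellate cell markers 6 fell, also over the list alone (adjusted p = 0.301 with an estimated correlation), among them Dcn (−2.21 ± 0.43) and Lrat (−2.13 ± 0.37).

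Of 18193 genes, 2462 passed, 1311 higher and 1151 lower, 1086 of them at least 2-fold. In 34.8% of genes the groups did not overlap, against 10% by chance. Further large rises were in Elapor1 (5.22), Kif5c, a kinesin (4.89), and Cidea, of lipid droplets (4.72). The largest falls were in Mup10, a urinary protein whose family shares probes (−4.70), Etnppl (−4.50), Slco1a1, an uptake carrier (−4.23), Hectd2os (−4.10), Hsd3b5, a steroid dehydrogenase (−4.07), Serpina4-ps1 (−3.99) and Obp2a (−3.82). Without Ha-ras tumour 1 the changes of Mup10, Etnppl, Slco1a1 and Hsd3b5 were −3.48, −3.50, −3.35 and −3.04, without Ha-ras tumour 3 those of Mup10 and Etnppl were −5.46 and −5.21, and without untreated control 3 that of Obp2a was −4.75. Of the genes above, Ccnb2, Ccna2 and Mki67 rose by 1.94, 1.33 and 1.38 without Ha-ras tumour 2, Sqle by 1.56 without untreated control 3 and Cyp17a1 by 3.36 without Ha-ras tumour 3, and Ccnb2 by 3.20 without Ha-ras tumour 1, where Clec4f and Cyp8b1 were at −1.67 and −2.89. Cyp7a1 was at −2.54 without untreated control 1 and −3.77 without untreated control 2. The Hsd3b5 call was lost without untreated control 2 or Ha-ras tumour 1 (adjusted p = 0.0603 and 0.0874). Ctnnb1 rose by 0.59 ± 0.11, though not past the threshold in its other probe sets (0.84 and 0.81) or their mean (adjusted p = 0.0623). Axin2 (−0.71 ± 0.46), Lgr5 (−1.61 ± 0.69) and Cyp2b10 (−0.16 ± 0.51) did not pass. Cyp2b10 was at −0.94 without Ha-ras tumour 1 and 0.51 without Ha-ras tumour 2. By camera 17 lists shifted, 1 of them with an estimated correlation, and fry called 15.

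**Figure D2:**
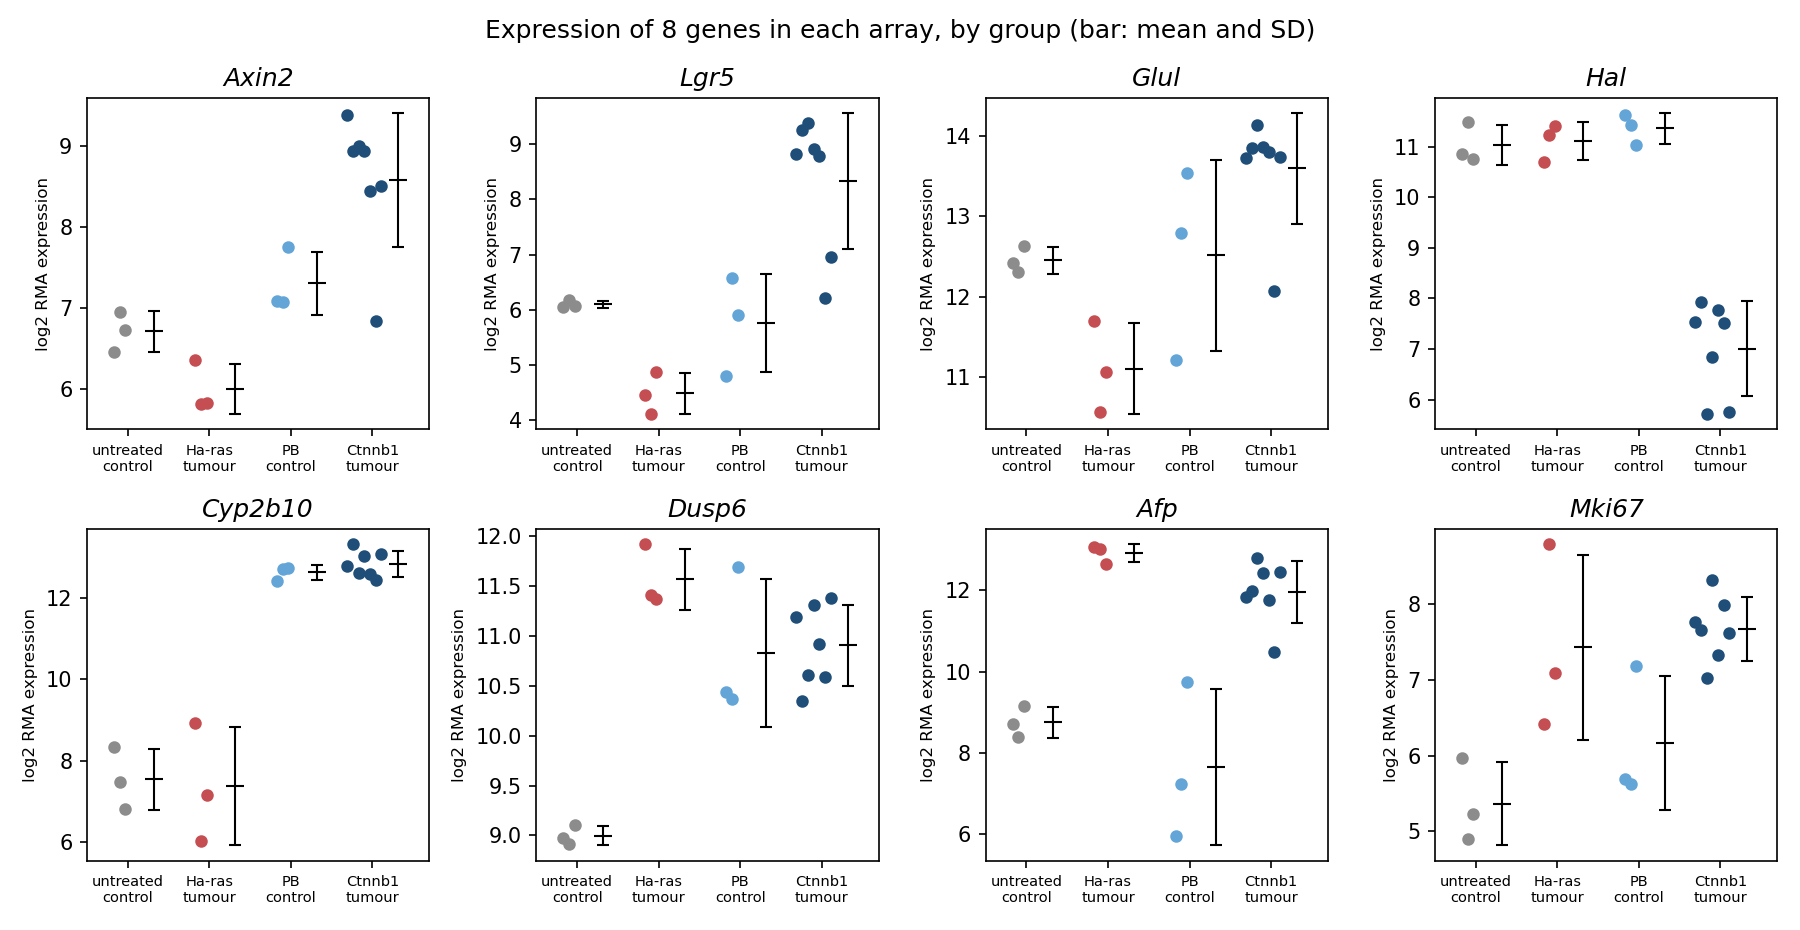
Log2 RMA expression (y axis) of 8 genes in each array, by group (x axis: 3 untreated controls, 3 Ha-ras tumours, 3 phenobarbital (PB) controls and 7 Ctnnb1 tumours); points are arrays, and bars show the mean and SD. Hal lay at 7.01 ± 0.93 in Ctnnb1 tumours against 11.11 ± 0.37 in Ha-ras tumours, and Dusp6 rose to 11.57 ± 0.31 in Ha-ras tumours, by 2.57 ± 0.32 over untreated controls.

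Whether the change from control to tumour differed between the tumour types was tested as the interaction over all 16 arrays. Mutation and phenobarbital go together here too, so a difference cannot be assigned to either. The pericentral genes parted most: the change was more positive in Ctnnb1 tumours for 12 of 16 and more negative for none (16 when adjusted over the list alone), with a median difference of 3.08. For Cyp7a1 the change was 1.62 ± 0.48 in Ctnnb1 tumours and −3.13 ± 0.57 in Ha-ras tumours, a difference of 4.75 ± 0.75. Its call in Ctnnb1 tumours was lost in 6 of the 10 runs that left out 1 array (adjusted p up to 0.175), with the Gapdh gap as a covariate (0.0668) and without phenobarbital control 6 and Ctnnb1 tumours 6 and 7 together (0.0607). The periportal list went the other way, with 6 of 16 more negative in Ctnnb1 tumours (11 when adjusted over the list alone; adjusted p = 0.0966 with an estimated correlation), such as Aldh1b1, an aldehyde dehydrogenase (−5.60 ± 0.83), and Hal (−4.43 ± 0.67). Of 18 ERK targets 9 were more negative in Ctnnb1 tumours (10 when adjusted over the list alone, where 1 was more positive), such as Spry2 (−3.15 ± 0.35) and Dusp6 (−2.49 ± 0.42). For Dusp6 more of this lay between the controls than between the tumours. With 1 array out, phenobarbital controls lay 1.40 to 2.06 above untreated controls, a call lost in 5 of 6 such runs. Ctnnb1 tumours lay at −0.76 to −0.48 against Ha-ras tumours.

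Of 13 Wnt targets 4 were more positive in Ctnnb1 tumours (8 when adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), among them Lgr5 (4.19 ± 0.90) and Tbx3, a transcription factor (3.14 ± 0.43). The differences for Axin2 (1.98 ± 0.60, adjusted p = 0.0679) and Glul (2.43 ± 0.69, adjusted p = 0.0518) passed without Ctnnb1 tumour 6 (2.27 and 2.68, adjusted p = 0.000579 and 0.00769), and that for Glul also without phenobarbital control 6 (2.94, adjusted p = 0.0186), while without phenobarbital control 4 Glul was at 1.78. The other probe set of Glul passed over all arrays (4.30, adjusted p = 0.0306), and that of Lgr5 did not (0.28). Bile acid genes were more positive in 4 of 13 (9 when adjusted over the list alone), with Cyp27a1, the sterol 27-hydroxylase, at 3.19 ± 0.31. CAR targets were more positive in 7 of 20 and more negative in 1 (10 and 2 when adjusted over the list alone), and fetal and tumour markers more negative in 5 of 15 (9 when adjusted over the list alone), with Akr1c18 at −4.57 ± 0.44. Immediate early genes were more negative in 5 of 12, also when adjusted over the list alone (adjusted p = 0.0844 with an estimated correlation), with Egr1 at −3.16 ± 0.34. The shifts of the pericentral, ERK, bile acid, CAR and fetal lists held with an estimated correlation (adjusted p = 0.0451 for each).

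Male-biased genes were more positive in Ctnnb1 tumours in 4 of 13 (7 when adjusted over the list alone, where 1 was more negative; adjusted p = 0.212 with an estimated correlation), with Cyp4a12a at 3.75 ± 0.51, and NRF2 targets in 3 of 12 (4 when adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with Gclm at 1.48 ± 0.23. Fatty acid and triglyceride synthesis was more negative in 6 of 21, also over the list alone (adjusted p = 0.288 with an estimated correlation), with Pnpla3 at −2.37 ± 0.39. In the citric acid cycle 4 of 20 were more positive, also over the list alone (adjusted p = 0.408 with an estimated correlation), with Cs, the citrate synthase, at 1.52 ± 0.26, and that shift was lost without phenobarbital control 6 (adjusted p = 0.160). Cell cycle genes did not part (0 of 26 passed, also over the list alone; median 0.15, adjusted p = 0.396).

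The interaction passed for 988 genes, 389 more positive and 599 more negative in Ctnnb1 tumours. Of these, 212 passed only in Ctnnb1 tumours, 611 only in Ha-ras tumours, 34 in both with the same direction, 83 in both with opposite directions and 48 in neither. Besides genes already named, the extremes were Orm2, an acute phase protein (4.74), Fam25c (4.38), Nptx1 (3.99), Cyp2c39 (3.96) and Snhg11 (3.93), and at the other end Rdh16f2 (−6.48), Wfdc15b (−5.91), Scn8a, a sodium channel (−5.43), Elapor1 (−5.18), Cdh1, E-cadherin (−5.05), and Bex1 (−4.93). Without untreated control 1 the count was 648. The calls of Orm2 and Cyp2c39 were lost without that control, untreated control 3 or Ha-ras tumour 2 (adjusted p up to 0.0566 and 0.0575). That of Bex1 was lost in 10 of 16 runs that left out 1 array (adjusted p up to 0.101). It was also lost with the Gapdh gap as a covariate (0.132) and with the fixed replicate block (0.0580). In the arrays of that block without it, the Orm2 call was lost too (0.0638). Without 1 array Orm2 lay between 3.96 and 5.42, Cyp2c39 between 2.95 and 4.80, Cyp7a1 between 4.16 and 5.39 and Bex1 between −5.80 and −3.77, and Cdh1 was at −4.36 without untreated control 1. With that covariate and with phenobarbital control 6 and Ctnnb1 tumours 6 and 7 left out together, both chosen after seeing the data, Glul passed (3.04 and 3.21), as did Axin2 in the latter (2.57). Ctnnb1 differed by −0.55 ± 0.14 (adjusted p = 0.0273), a call lost without phenobarbital control 6, untreated controls 1 or 3, or Ha-ras tumours 1 or 2 (adjusted p up to 0.0805), with the covariate (0.0783) or without the 3 arrays (0.0511), and its other probe sets did not pass (0.31 and −0.20), nor did the mean of all (−0.15). The Ctnnb1 call was also lost in the arrays of the fixed block, fitted without the block (adjusted p = 0.0822). By camera 18 lists parted, 5 of them with an estimated correlation, and fry called 14.

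**Figure D3:**
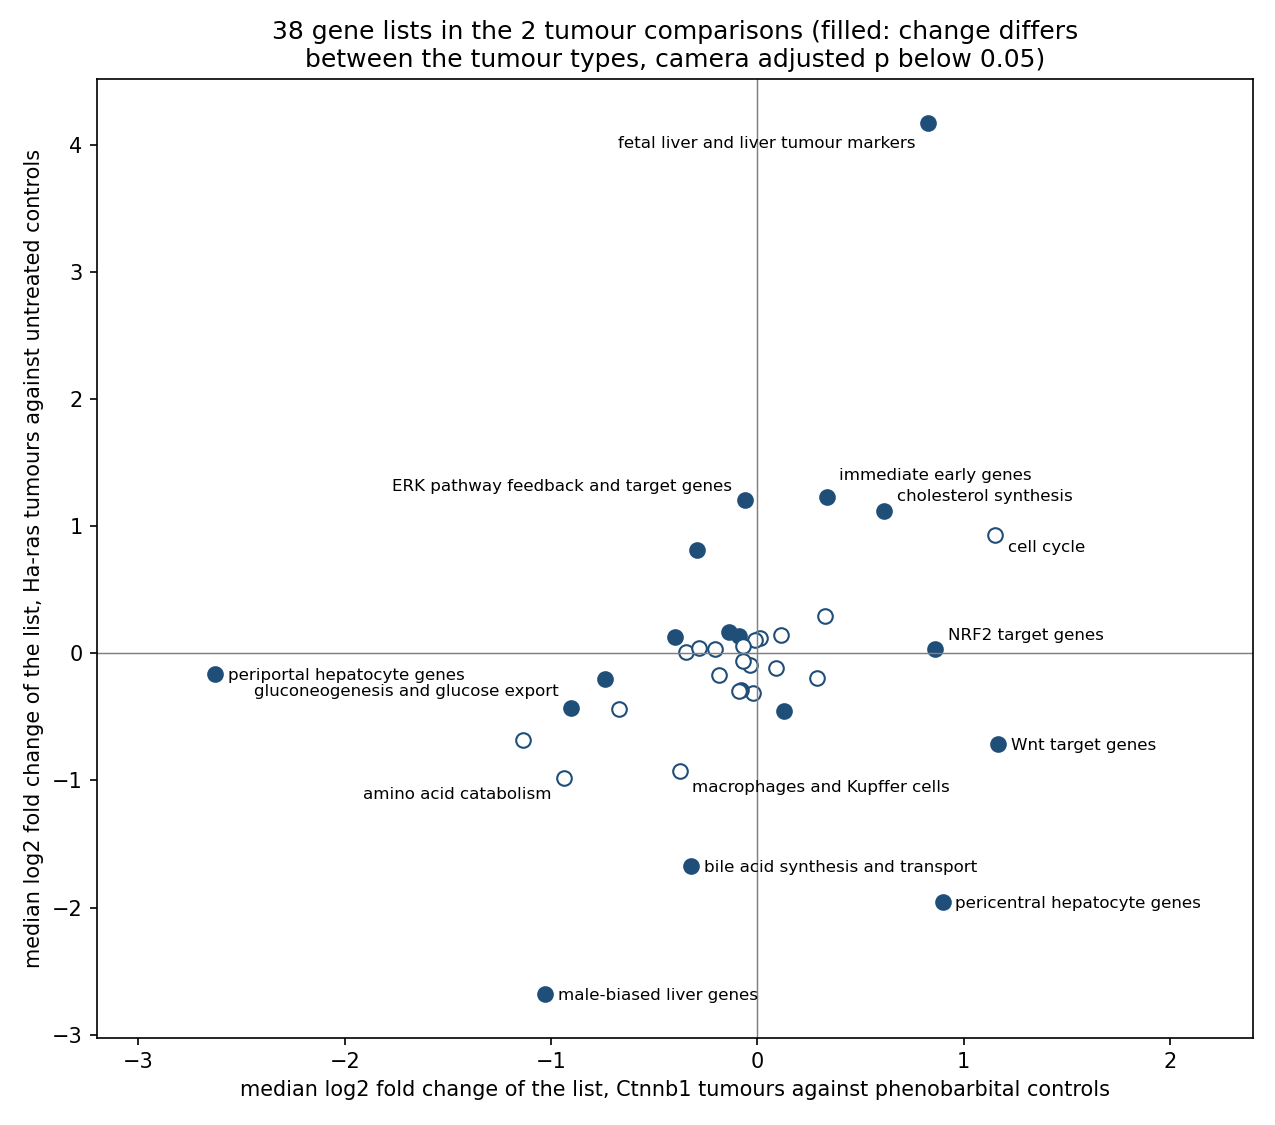
Median log2 fold change of each of 38 gene lists in Ctnnb1 tumours against phenobarbital control liver (x axis) and in Ha-ras tumours against untreated control liver (y axis). Filled points are the 18 lists whose change differed between the tumour types by camera; the pericentral list lay at 0.90 and −1.95, and the periportal list at −2.63 and −0.16.

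Calls shared by the 2 tumour types were counted, since the comparisons use separate arrays. Both rest on 1 fit with a common spread per gene, so the numbers from independent lists and Fisher's test are descriptions only. Afp rose in both, by 4.33 ± 0.59 and 4.17 ± 0.70, Ccnb2 by 2.27 ± 0.44 and 2.58 ± 0.52, and Etnppl fell by 5.23 ± 0.61 and 4.50 ± 0.72. Higher in both were 338 genes, against 79.6 from independent lists, and lower in both were 290, against 68.8. Opposite calls were fewer than from independent lists, 38 and 45 against 69.9 and 78.3, but at a threshold of 0.01 the 9 and 12 were not told apart from 12.7 and 18.1 (Fisher's exact test, p = 0.384 and 0.179). The fold changes correlated across genes with Pearson's r = 0.389 and Spearman's rho = 0.310, where genes are not independent replicates. In all 3943 genes passed in either comparison and 711 in both, 628 of them in the same direction.

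Non-tumour liver with phenobarbital was compared with non-tumour liver without it (n = 3 and n = 3). CAR targets were higher under phenobarbital. Cyp2b10 rose from 7.54 ± 0.76 to 12.62 ± 0.18, a 33.8-fold difference, and Cyp2c55, another P450, from 8.19 ± 0.50 to 12.09 ± 0.30. Of 20 CAR targets 4 rose and none fell over all genes (13 rose when adjusted over the list alone), with a median of 1.03, and the shift held with an estimated correlation (adjusted p = 0.00509). The other 2 were Cyp2c65 (4.80 ± 0.85) and Gstm3, a glutathione transferase (1.88 ± 0.33). Prss8, a protease, Mmp13, a collagenase, and Dusp6 also rose (2.38, 2.37 and 1.83). Obp2a fell by 3.23 and Slc22a7, an organic anion carrier, fell by 2.67. Aqp4 (−1.95), Akr1c18 (−1.88), Kcnt2 (−1.27), Klf1, an erythroid factor (−1.24), and Inhbe (−1.08) fell less. Glul differed by 0.06 ± 0.53, Axin2 by 0.59 ± 0.46 and Lgr5 by −0.34 ± 0.69, and none of these 3 passed; Glul was at −0.45 without phenobarbital control 6 and 0.71 without control 4, and Lgr5 at 0.14 without control 4.

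In 18193 genes 39 passed, 24 higher and 15 lower, and the groups did not overlap in 18.8% of genes, against 10% by chance. A further 7 lists shifted by camera with no member passing over all genes, and none of these held with an estimated correlation (adjusted p = 0.721 for each). Cholesterol synthesis was higher (median 0.64; 7 of 18 members rose when adjusted over the list alone), as were glycolysis (0.26; 0 of 17), female-biased genes (0.64; 3 of 10) and interferon response (0.51; 2 of 11). Acute phase genes were lower (−0.38; 3 of 17 fell when adjusted over the list alone), as were fatty acid oxidation (−0.26; 2 of 19) and male-biased genes (−0.62; 0 of 13), each also with an adjusted p of 0.721 with an estimated correlation. The cholesterol shift was lost without untreated control 3 (adjusted p = 0.0759) and that of fatty acid oxidation without phenobarbital control 6 (0.0546). The female-biased, male-biased and interferon shifts were each lost without phenobarbital control 5 (0.332, 0.263 and 0.190) or untreated control 2 (0.216, 0.195 and 0.148), and the last 2 also without phenobarbital control 4 (0.0512 and 0.145). Without dim genes the female-biased (0.121) and interferon (0.0545) shifts were lost. The count of genes moved with every array left out: 3 without phenobarbital control 4, 68 without control 5, 9 without control 6, and 8, 15 and 6 without untreated controls 1, 2 and 3, and of the 14 genes named only Cyp2b10 and Cyp2c55 passed throughout. Obp2a was at −4.17 without untreated control 3 and Prss8 at 1.74 without phenobarbital control 6. With the Gapdh gap as a covariate 4 genes passed, and the calls of 12 of those 14 ended. Without phenobarbital control 6 and Ctnnb1 tumours 6 and 7 together 8 of the 14 ended, and Afp passed (−2.16, adjusted p = 0.0489). Both alternatives were chosen after seeing the data. Afp had not passed over all arrays, and was at −0.27 without phenobarbital control 4.

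The tumours were last set side by side, where mutation and phenobarbital differ together (n = 7 and n = 3). All 16 pericentral genes were higher in Ctnnb1 than in Ha-ras tumours, with a median of 2.99, and Glul differed by 2.49 ± 0.44, Axin2 by 2.57 ± 0.38 and Lgr5 by 3.85 ± 0.58 (0.09 in its other probe set, not passing). Of 13 Wnt targets 9 were higher (10 when adjusted over the list alone; adjusted p = 0.118 with an estimated correlation). Of 20 CAR targets 17 were higher and none lower (17 and 1 when adjusted over the list alone), led by Cyp2b10 at 5.44 ± 0.43 (4.78 without Ha-ras tumour 2 and 6.22 without Ha-ras tumour 1) and Cyp2c55 at 5.31 ± 0.31. Lower in Ctnnb1 tumours were 10 of 18 ERK targets (11 when adjusted over the list alone, where 1 was higher), such as Spry2 (−3.07 ± 0.23), 11 of 16 periportal genes (12 and 1 higher; adjusted p = 0.118 with an estimated correlation), such as Hal (−4.10 ± 0.43), and 7 of 15 fetal and tumour markers (8 over the list alone), such as Akr1c18 (−6.45 ± 0.28). Higher were also 8 of 12 NRF2 targets (adjusted p = 0.0805 with an estimated correlation), such as Gsta4, a glutathione transferase (1.54 ± 0.21), and 7 of 13 bile acid genes (10 over the list alone), such as Cyp27a1 (2.89 ± 0.20). The pericentral (adjusted p = 0.0306), CAR (0.00186), fetal (0.0306), ERK and bile acid lists (0.0383 each) held with an estimated correlation.

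Between the tumours 2750 genes passed, 1312 higher and 1438 lower in Ctnnb1 tumours, 898 of them at least 2-fold. The groups did not overlap in 16.2% of genes, against 1.67% by chance. The largest differences with Ctnnb1 higher, after the P450 genes, were in Snhg11 (4.72), Kcnk1, a potassium channel (4.67), Nptx1 (4.64), Cyp2c39 (4.21) and Nxpe2 (4.18). With Ha-ras higher they were in Wfdc15b (−7.18), Akr1c18, Elapor1 (−6.08), Spink1 (−5.90), Rdh16f2 (−5.89), Aldh1b1 (−5.29) and Tspan8 (−5.20). Ctnnb1 differed by −0.46 ± 0.09 (−0.31 and −0.71 in its other probe sets and −0.50 in the mean of all, none passing). Dusp6 (−0.66 ± 0.27), Afp (−0.95 ± 0.59) and Mki67 (0.24 ± 0.44) did not pass. Mki67 was at −0.27 without Ha-ras tumour 1 and 0.92 without Ha-ras tumour 2. Of the other probe sets of Afp 1 passed (−1.47, adjusted p = 0.0449). Dusp6 passed without phenobarbital control 6 and Ctnnb1 tumours 6 and 7 (−0.69, adjusted p = 0.0256). Of these 3 genes, 1 passed with the fixed replicate block of tumours 1 to 3. The count was 1745 without Ha-ras tumour 1. By camera 18 lists shifted, 5 of them with an estimated correlation, and fry called 16.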

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

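The tests of degraded RNA, tumour tissue and time of day in phenobarbital control 6, of a swap and of a Ha-ras type tumour for Ctnnb1 tumour 6, and of degraded RNA in Ctnnb1 tumour 7 were chosen only after the result was seen, while the splits, the test of non-tumour liver and the test of macrophages were set before. The splits, the lists, the comparisons and the other settings tried, apart from those named as added, were chosen before the data were examined. An exception was the set of named genes rerun, widened from shifted lists to all lists after values were seen. The tests of non-tumour liver and of macrophages concern arrays picked out from these data. They were thus set before their own results, but not before the data were examined.

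Phenobarbital control 6 stood apart from the other 2 phenobarbital controls. Its Gapdh gap of 2.70 lay above the range of −0.15 to 0.32 in the other 15 arrays, as degraded RNA in that library may give. Tumour tissue in that piece stays open. The 30 genes used were those raised most from untreated controls to Ctnnb1 tumours, without CAR targets and genes called between controls. Smaller effects of phenobarbital may remain in them. They implied a median share of tumour RNA of 0.124 (quartiles 0.0215 and 0.348). For control 5 relative to control 4 the median was 0.0641 and the upper quartile 0.114. Another time of day at sampling also stays open, since 10 of 14 clock genes lay outside controls 4 and 5 on the side that 1 shift of phase gives and 3 on the other, 1 fewer than the 11 set for it, and the bound against it was set again after that count was seen. The count leaves out the sizes: the 10 lay outside by at least 0.478 (log2) and the 3 by at most 0.124. No biological explanation was tested.

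Ctnnb1 tumour 6 had Wnt target and pericentral levels near control liver. Non-tumour liver in that sample is argued against: the 30 genes most lowered in the other 6 tumours implied a median share of normal RNA of 0.00123 (quartiles −0.0372 and 0.0559), where its Wnt targets would need 0.966. A swap with phenobarbital control 6 is argued against by that control lying 1.20 times as far from the other Ctnnb1 tumours as from controls 4 and 5. A Ha-ras type tumour is argued against by its mean over the ERK list of 6.66, against 7.42 to 7.81 in Ha-ras tumours (SD 0.196) and 6.48 to 6.81 in the other Ctnnb1 tumours. Another wrong label stays open, and no biological explanation was tested.

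NRF2 target genes were highest in Ctnnb1 tumour 7, 1.32 above the mean of the other 6 tumours. Degraded RNA is argued against by a Gapdh gap of −0.15, the lowest of the 16 arrays. More macrophages are argued against by the macrophage list, which lay 0.16 below the mean of the other tumours (difference −0.16; 8.16 against a highest other of 8.65). No biological explanation was tested.

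Among 93 tests of 55 genes and 38 list means in the 7 Ctnnb1 tumours, 10 had 1 array far from the other 6, where chance gives about 0.05 of the tests, and 5 of the 10 were in tumour 6 and 2 in tumour 7. In tumour 6 these were Axin2 at 6.84 (others 8.44 to 9.38), Gipc2 at 7.75 (9.64 to 11.06), Glul at 12.07 (13.72 to 14.14), Nxpe2 at 8.39 (9.97 to 10.86) and the mean of the pericentral list at 11.39 (12.33 to 12.79). In tumour 7 they were the mean of the bile acid list at 10.93 (11.27 to 11.36) and that of the T and NK cell list at 6.14 (5.10 to 5.53). In tumour 2 they were Aplnr at 4.29 (6.56 to 8.10) and Kcnt2 at 3.55 (2.61 to 2.97), and in tumour 3 the mean of the clock genes at 7.37 (7.02 to 7.16).

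The change from control to tumour differed between the tumour types for 988 genes and 18 lists by the interaction, and 83 of the 988 passed in both tumour types with opposite directions. Of the 14 genes named for it 12 had opposite signs, passing or not, but they were taken for their large differences, which favours opposite signs. In data outside the comparisons, the hybridisation spike-ins of phenobarbital control 6 had a mean of 12.03 (10.72 to 11.45 in the other arrays). Of 10092 probe sets with no single gene name, 311 passed between Ctnnb1 tumours and their controls and 340 between Ha-ras tumours and theirs.

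Of 100 splits of the arrays into groups of the same sizes, only the real 1 gave as many genes as observed in 3 comparisons. The share of such splits was thus under 0.05, but this number of splits cannot exclude chance. The Ctnnb1 comparison gave 2192 against 97 in the highest other split, which exchanged Ctnnb1 tumour 6 and phenobarbital control 6. The interaction gave 988 against 866, in a split that exchanged phenobarbital control 5 and untreated control 2. Its count thus hardly parted the real labels from that split. Ctnnb1 against Ha-ras tumours gave 2750 against 351. For Ha-ras tumours against their controls (2462, highest other 2) and for the controls (39, highest other 1) the 10 splits are too few for a share under 0.05.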

How the results depend on the processing

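The joint omission of phenobarbital control 6 and Ctnnb1 tumours 6 and 7, the Gapdh gap as a covariate, and the arrays of a block without it, were chosen after seeing the data. The other alternatives were planned. The covariate rests mostly on phenobarbital control 6, so it is not independent of leaving out that array. Counts stayed within 1.5 times under dim genes left out, the other choices of probe set per gene, normalization, trended spread and a random block, but leaving out dim genes ended 14 of 73 list shifts and the mean of all probe sets 3 of 75, and scaling moved the median of all genes by −0.0436 to 0.0375. The count for Ctnnb1 tumours against their controls (2192) was 804 with a fixed replicate block, which uses only arrays with a partner of the same number, and 908 in those arrays without the block, 1383 with the 3 arrays out and 836 with the covariate, and between 1337 (without phenobarbital control 6) and 2219 (without control 5) with 1 array out. With a 2-fold minimum, which asks more of each gene, it was 596, that for Ha-ras tumours 1086 and that between tumours 898. Array weights gave 3775 for Ha-ras tumours (2462), 1547 for the interaction (988) and 242 for the controls (39). The interaction lay between 648 (without untreated control 1) and 1177 (without Ctnnb1 tumour 7), the tumours (2750) between 1745 (without Ha-ras tumour 1) and 2883 (without Ctnnb1 tumour 7), with 1668 in a block of tumours 1 to 3 and 2040 in those arrays without it, and Ha-ras tumours between 1698 and 2273. The controls gave 21 with the 3 arrays out, 4 with the covariate, 19 with only their own arrays, and between 3 (without phenobarbital control 4) and 68 (without control 5) with 1 array out. Among the Ctnnb1 samples 0 of 3 pairs of tumour and control with the same number correlated above 0.1. In Ha-ras 2 of 3 pairs did (0.399 and 0.238, the other 0.030), so samples of the same number may be paired there. The check used deviations from group means, and in the phenobarbital controls these largely carry the departure of control 6. It therefore leaves open whether the Ctnnb1 samples are paired. With a fixed replicate block the Ha-ras count was 2324. The block of tumours 1 to 3 joins tumours with and without phenobarbital, which the labels do not link. It therefore tests no known pair of samples. An estimated correlation left 0 of 14 shifted lists in Ctnnb1 tumours, 1 of 17 in Ha-ras tumours, 5 of 18 in the interaction, 1 of 8 in controls and 5 of 18 between tumours; the control lists numbered 1 by fry, 13 with the 3 arrays out, and 5 (without untreated control 2) to 12 (without untreated control 1). The 628 shared calls were 252 at a threshold of 0.01, 388 with the block and 418 in its arrays without it. Except where the alternative itself asks more of a gene or uses fewer arrays, the cause was not tested.

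With each array left out, the named genes that passed kept their sign, while 9 changes that had not passed turned: Ctnnb1 and Dusp6 in Ctnnb1 tumours, Cyp2b10 in Ha-ras tumours, Afp, Cyp2b10 and Mki67 in the interaction, Glul and Lgr5 between controls, and Mki67 between tumours. The calls of 56 of 94 named genes held in every run in the Ctnnb1 comparison, 73 of 96 in Ha-ras, 53 of 75 in the interaction, 2 of 14 in controls and 91 of 122 between tumours; this set was widened from members of shifted lists to those of all lists after values were seen. Without 1 array the fold moved by over 1.5 times in 7, 21, 8, 2 and 9 of them. The covariate ended 70 of 401 calls of named genes (42 of 94 in the Ctnnb1 comparison), the 3 arrays out 44 of 305, the mean of all probe sets 28 of 401, and the fixed blocks 44 of 94 in the Ctnnb1 comparison, 5 of 96 in Ha-ras, 11 of 75 in the interaction and 28 of 122 between tumours, against 38, 3, 14 and 24 in the same arrays without the block. Of genes described in Ctnnb1 tumours, Abcc4, Axin2, Clec4f, Cyp7a1, Dlk1, Glud1, Lgr5, Lss, Mki67 and Nsdhl did not pass in those arrays with or without the block, Arg1, Ccnb2, Fbp1, Gulo, Sdha, Sdhb and Ube2c only with it, and Folr2 and Myc only without it. In the block's arrays 5 list shifts were lost with the block and without it: fatty acid oxidation in Ha-ras tumours (adjusted p = 0.0641 and 0.0722), endothelial cells in the interaction (0.0828 and 0.142), and the cell cycle (0.0653 and 0.134), interferon (0.358 and 0.407) and endothelial (0.0677 and 0.116) lists between tumours. Of named genes that passed and had more than 1 probe set, all probe sets gave the same call in 16 of 41 in the Ctnnb1 comparison, 18 of 38 in Ha-ras, 11 of 33 in the interaction, 2 of 3 in controls and 24 of 55 between tumours. Another probe set had the same sign without passing 126 times, among them those of Lgr5 (0.19) and Axin2 (0.15) in Ctnnb1 tumours, and passed where the kept 1 had not 3 times (Glul in Ctnnb1 tumours, 2.34, and in the interaction, 4.30, and Afp between tumours, −1.47). The cause was tested for none of these differences between probe sets, nor for the 34 times that another probe set had the other sign without passing. Those with the other sign were, in Ctnnb1 tumours against their controls, Aqp4 (0.12), Idh3a (−0.15), Ptprb (0.047), Slc13a3 (−0.17) and Ighm (−0.075, −0.15, −0.022, −0.036, −0.27, −0.0081 and −0.00686). In Ha-ras tumours they were Sdha (0.069), Tbx3 (0.022) and Znrf3 (0.020). In the interaction they were Acly (0.20 and 0.18), Ctnnb1 (0.31), Idh2 (−0.37), Ighm (−0.11, −0.17, −0.043 and −0.34), Scn8a (0.17), Sox9 (0.16) and Spry4 (0.45). Between tumours they were Bub1b (−0.060), Ighm (−0.046, −0.026, −0.076, −0.10 and −0.087), Sox9 (0.079), Spry4 (0.14) and Vegfa (0.0070). The number of arrays limits these counts, and signal near background limits dim genes.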

Other observations

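The list tests below were set before the data were examined, while the genes described were picked from those the naming rule allows after their values were seen. Citric acid cycle genes went both ways in Ctnnb1 tumours, with 5 of 20 risen and 3 fallen (5 and 6 when adjusted over the list alone; list adjusted p = 0.937). Idh3a, a subunit of isocitrate dehydrogenase, rose by 1.24 ± 0.20 (−0.15 in another probe set), while Sdhb and Sdha, subunits of succinate dehydrogenase, fell by 0.69 ± 0.13 and 0.62 ± 0.13. The Sdha call was lost with the Gapdh gap as a covariate (adjusted p = 0.0665) or the mean of all probe sets (0.0799). In Ha-ras tumours 6 of 20 fell and none rose (7 over the list alone; median −0.29, adjusted p = 0.294 with an estimated correlation), with Sdha down by 0.67 ± 0.15 (0.07 in another probe set; adjusted p = 0.0504 for the mean of all). Urea cycle genes fell in Ha-ras tumours in 2 of 11, also over the list alone (median −0.68, adjusted p = 0.267 with an estimated correlation): Asl, the argininosuccinate lyase, by 1.47 ± 0.20 and Slc25a15, the ornithine carrier, by 1.13 ± 0.19. Fatty acid oxidation had 2 of 19 fallen there (5 over the list alone; median −0.31, adjusted p = 0.646 with an estimated correlation), a shift lost without Ha-ras tumour 2 (adjusted p = 0.231) or untreated controls 1 (0.0602) or 3 (0.0718), without dim genes (0.0531) and with the mean of all probe sets (0.103).

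Among liver transcription factors Nr1i3, the gene of CAR, fell by 2.46 ± 0.29 in Ha-ras tumours and Nr1h4, the bile acid receptor, by 0.87 ± 0.17, while Foxa3 rose by 1.07 ± 0.21; Cebpa fell in Ctnnb1 tumours by 0.92 ± 0.13. The list did not shift in either (adjusted p = 0.192 and 0.280). Il1rn, the interleukin-1 receptor antagonist, rose by 3.60 ± 0.41 in Ha-ras tumours, where 2 acute phase genes rose and 3 fell (adjusted p = 0.610). Gyg, the primer of glycogen, rose in both tumour types (0.94 ± 0.15 and 0.87 ± 0.18), with glycogen metabolism at an adjusted p of 0.332 and 0.110. Alas2, of heme synthesis in red cells, fell by 2.31 ± 0.38 in Ha-ras tumours (erythroid list adjusted p = 0.734). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.30 ± 0.19 in Ctnnb1 tumours (hypoxia list adjusted p = 0.937).

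Between the tumours further lists shifted by camera. Secreted plasma proteins were lower in Ctnnb1 tumours (6 of 21 passed), as were immediate early genes (6 of 12), gluconeogenesis (5 of 10, with 1 higher), endothelial markers (1 of 13) and fatty acid synthesis (6 of 21, with 1 higher), with an adjusted p of 0.467, 0.197, 0.198, 0.551 and 0.551 with an estimated correlation. Macrophage markers (3 of 14), male-biased genes (6 of 13, with 1 lower), the cell cycle (4 of 26, with 1 lower), the citric acid cycle (6 of 20, with 2 lower) and the interferon response (3 of 11) were higher. With an estimated correlation these 10 lists had an adjusted p between 0.197 and 0.622, and single arrays ended 7 of these shifts. Ha-ras tumour 1 ended those of macrophages (adjusted p = 0.105), the cell cycle (0.201), the citric acid cycle (0.0668), fatty acid synthesis (0.0749) and interferon response (0.148), and Ha-ras tumour 3 those of gluconeogenesis (0.0531), fatty acid synthesis (0.0618), the cell cycle (0.0678) and endothelial markers (0.260). Ha-ras tumour 2 and Ctnnb1 tumours 4, 6 and 7 ended the interferon shift (0.0598 to 0.0854), Ctnnb1 tumours 2 and 6 that of fatty acid synthesis (0.0538 and 0.0695), and Ctnnb1 tumour 7 that of endothelial markers (0.104). Leaving out dim genes ended the shifts of fatty acid synthesis (0.0524), the citric acid cycle (0.0838), the cell cycle (0.162), interferon response (0.181) and endothelial markers (0.0538). Phenobarbital control 6 and Ctnnb1 tumours 6 and 7 left out together, chosen after seeing the data, ended those of fatty acid synthesis (0.128), the cell cycle (0.0550), interferon response (0.125) and endothelial markers (0.0803), and the mean of all probe sets that of interferon response (0.0547). In the interaction the female-biased (2 of 10 more negative), cholesterol (1 of 18), gluconeogenesis (1 of 10), glycolysis (1 of 17), cholangiocyte (2 of 6) and endothelial (0 of 13) lists shifted with an adjusted p between 0.209 and 0.617 with an estimated correlation. Single arrays ended 5 of these 6 shifts: phenobarbital control 5 the female-biased (0.0620), untreated control 3 the cholesterol (0.179), Ha-ras tumour 3 the gluconeogenesis (0.0541), Ha-ras tumour 1 the glycolysis (0.0689), and 8 of the 16 arrays the endothelial shift (up to 0.301). Leaving out dim genes ended the glycolysis (0.0783), female-biased (0.0951) and endothelial (0.109) shifts, and the mean of all probe sets the last (0.112).

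Lists that shifted in neither tumour against its control, with the adjusted p in Ctnnb1 and Ha-ras tumours, were glycolysis (0.434 and 0.106), the pentose phosphate pathway (0.907 and 0.610), secreted plasma proteins (0.907 and 0.165), the interferon response (0.195 and 0.207), clock genes (0.241 and 0.692), T and NK cells (0.310 and 0.640), B and plasma cells (0.280 and 0.734), neutrophils (0.470 and 0.668), adipocytes (0.907 and 0.207) and exocrine pancreas (0.937 and 0.692). The clock list holds genes of opposite phase, so a shift of phase could cancel out in its test. Wnt targets (0.172), periportal genes (0.668), NRF2 targets (0.692), endothelial cells (0.748) and cholangiocytes (0.379) did not shift in Ha-ras tumours, nor did ERK targets (0.907), immediate early genes (0.219), bile acid genes (0.907), female-biased genes (0.773), fatty acid synthesis (0.387) and fatty acid oxidation (0.907) in Ctnnb1 tumours.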
